A study of Bos taurus with 8 samples.

How the data were processed

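Transcripts were measured by RNA sequencing in 8 samples of day-15 bovine conceptuses, 4 control and 4 with FGF2, LIF and IGF1 added, from stranded poly-A libraries per the labels. The submitters' processing notes name FastQC, HISAT2, featureCounts and edgeR and the genome build ARS-UCD1.2. The versions, the strand setting of the counting and the treatment of reads with several positions are not given in the sources used here. The deposited table holds 15267 genes with Ensembl identifiers, exon coordinates and 8 columns of values. Gene names were taken from the deposited table, which names 13181 of its genes and leaves 2086 unnamed. The reference list of gene names at hand belongs to another assembly, ARS-UCD2.0, and 0 identifiers matched it.

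Per the values of the deposited table, the signal in each sample column is CPM of a TMM-scaled library total, made by the authors: every value is a whole multiple of 1 step per column, with 100% of the values whole within 0.001 and a largest distance of 4.9e-09. The whole reads recovered in this way give TMM factors equal to those of edgeR, and 1 read is between 0.00647 and 0.00987 CPM. The read totals were 108851495 to 152570016 per library. The lowest total of a gene over all samples was 112 reads, so genes of low level had been left out before deposit. Even numbers made up 57.8% of the recovered counts from 1 to 20. Intervals and floors from counts (3 reads of a library where 0 were seen) cover counting error alone. The 10 most abundant genes took 8.40 to 12.9% of a library's reads, and the 19 mitochondrial genes 3.21 to 6.68%. The authors' deposited table also gives a log2 fold change and mean log2 level, a likelihood ratio score, and a p-value with its adjusted value for each gene, per the file headers. A likelihood ratio test with robust observation weights, run on the recovered reads, gave log2 fold changes with a correlation of 0.999998 with the authors' deposited table over 15267 genes (largest absolute difference 0.148) and called all of the 32 genes listed there plus 1 more.

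The samples were grouped by the treatment label. The groups, the tests, the 29 gene lists, the rule for named genes and most of the alternative settings were chosen before the data were examined. The plan named the edgeR quasi-likelihood test for counts and limma for normalized values. Since the deposited values are normalized, limma 3.58.1 (eBayes with trend) was used on log2(value + 0.5) for the 11897 genes with a value of at least 1 in at least 4 samples, and the edgeR 4.0.16 test on recovered reads became an added alternative. The Benjamini-Hochberg method was used over all tested genes, with a threshold of 0.05, and tests were two-sided. Camera was run on the same scale, in place of the planned log2 CPM with a prior count of 2, for the lists with at least 5 tested members. It used a preset correlation of 0.01, and was run again with an estimated correlation, with fry beside it. Of 951 symbols in the lists, 821 were in the deposited table. List means per sample were compared by an exact permutation test over 70 assignments, and the share of the sum of squares between groups by an exact test over 35 splits. R 4.3.3 and DESeq2 1.42.0 were also used.

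Named genes were the 6 genes with a symbol of smallest p on each side, since none passed the threshold, every tested member of the list of treatment ligands and receptors, and the 2 members of smallest p of each other list. The member of highest mean CPM was added for the epiblast, blood, leukocyte and endometrium lists. Genes named outside this rule are said to be chosen after their values were seen. The values of 1 gene that the rule names are not reported here. XIST was not analysed here.

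The titles share the numbers 20, 3M and 4M between the groups, and no label says what they mark. Deviations from the group means correlated at 0.133, 0.351 and 0.359 for the 3 pairs of equal number, each over 0.1, and the number was fitted as a block on these 6 samples as an alternative. The correlations also followed the last character of the title: they averaged 0.25 between samples with the same last character and -0.25 between others, and 4 of 6 samples correlated best with their own number. Samples of equal number always share that character, and every control and FLI combination sharing it was over 0.1 (0.133 to 0.359). A pairing by number therefore cannot be told apart from likeness by the last character.

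The scripts were tested on simulated reads with the real mean and spread of each gene for the comparison of FLI with control. Each gene was drawn on its own, without the variation that genes share between samples. The recovery rates therefore need not hold for the real samples. Of 50 genes changed at each fold, limma recovered 18% at a 2-fold change, 72% at 4-fold, 94% at 8-fold and 90% at 16-fold among 11980 genes, with 6 false genes in 143 calls. The likelihood ratio test with robust observation weights recovered 42%, 86%, 100% and 100% among 15267 genes, with 121 false genes in 285 calls. With nothing changed, limma and the quasi-likelihood test called 0 genes and the likelihood ratio test called 35. Alternatives covered the normalization, tool, filter, pseudocount, scale, threshold, title number as a block, last character of the title and epiblast list mean as covariates, each sample left out in turn, and subsets of samples.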

Results

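RNA was sequenced from 8 samples of bovine conceptuses at day 15, the filamentous stage at which the trophoblast elongates before it attaches to the uterus. The labels describe each sample as a conceptus-half grown through in vitro embryo development. In 4 samples FGF2 (a fibroblast growth factor), LIF (leukemia inhibitory factor) and IGF1 (an insulin-like growth factor) had been added, and this group is called FLI. The other 4 samples were controls. The control samples are called 10, 20, 3M and 4M and the FLI samples 20, 3M, 4M and 50, as in their titles. The libraries held 108851495 to 152570016 reads assigned to the 15267 genes of the deposited table. Control 10 had 124128056 reads, control 20 had 152570016, control 3M had 130581695 and control 4M had 128157279. FLI 20 had 118197696 reads, FLI 3M had 136915876, FLI 4M had 140460601 and FLI 50 had 108851495. Levels are given as the authors' TMM-scaled CPM, reads of a gene relative to the scaled library total, as mean ± SD with n = 4 per group.

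The comparison of FLI with control asked how the 3 factors change the conceptus transcriptome, in a study whose title concerns survival and elongation of embryos after slow-rate freezing. Trophoblast secretory products had a higher mean in FLI for 11 of 11 tested genes (camera adjusted p = 3.87e-08, and adjusted p = 0.636 with an estimated correlation). Among them PAG2, a pregnancy-associated glycoprotein of the trophoblast, was at 403 ± 203 CPM in control and 1767 ± 774 CPM in FLI. In the mean level of these secretory products FLI 4M lay inside the control range. ASS1, an enzyme of the citrulline to arginine cycle, was at 19.8 ± 9.35 CPM in control and 82.1 ± 29.0 CPM in FLI. NOS2, the inducible nitric oxide synthase that uses arginine, was at 0.443 ± 0.296 CPM in control and 21.0 ± 16.5 CPM in FLI. Genes of the epiblast and embryonic disc were lower for 15 of 17 members (adjusted p = 0.00119, and adjusted p = 0.79 with an estimated correlation), such as POU5F1, a pluripotency factor, at 18.5 ± 12.1 CPM in control and 7.51 ± 7.85 CPM in FLI. Low POU5F1 was found in FLI 20 and FLI 50 (1.42 and 1.01 CPM). Among samples with titles ending in M this list was higher in FLI, by a mean log2 of 0.19. Which tissue each conceptus-half held was not tested. No single gene passed the adjusted threshold in the planned test: limma called 0 of 11897 tested genes at an adjusted p of 0.05, and the smallest adjusted p was 0.97.

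The 6 named genes of smallest p among those higher in FLI were MAPK8IP2, ASS1, NOS2, LOXL4, PAG2 and GSE1, and for each of them all 4 FLI samples lay above all 4 controls. MAPK8IP2 (ENSBTAG00000030179), a scaffold protein of JNK signalling, lies on chromosome 5 at 119917200 to 119927553 of ARS-UCD1.2. It was at 6.53 ± 2.03 CPM in control and 22.1 ± 9.10 CPM in FLI, a log2 difference of 1.64 (SE 0.33). ASS1 (ENSBTAG00000020747, chromosome 11, 100770166 to 100822252) differed by a log2 of 2.09 (SE 0.42), with a 95% confidence interval of 1.13 to 3.04. NOS2 (ENSBTAG00000006894, chromosome 19, 19388579 to 19429569) differed by 3.95 (SE 0.82). Its FLI values ranged from 1.83 CPM in FLI 4M to 36.5 CPM in FLI 3M, against at most 0.802 CPM in a control. LOXL4, a lysyl oxidase family enzyme of the extracellular matrix, was at 6.42 ± 1.39 CPM in control and 14 ± 3.54 CPM in FLI, a log2 difference of 1.06 (SE 0.23). PAG2 (ENSBTAG00000033096, chromosome 29, 37571936 to 37581505) differed by 2.13 (SE 0.48). PAG genes form a multicopy family, so the assignment of reads to a single copy is uncertain. GSE1 was at 10.8 ± 1.17 CPM in control and 17.0 ± 1.44 CPM in FLI, a log2 difference of 0.63 (SE 0.14).

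The 6 named genes of smallest p among those lower in FLI were H2BC15, JUND, CDH26, UGT8, KRT80 and CRISPLD1. H2BC15 (ENSBTAG00000031886, chromosome 23, 30972348 to 30976581), a histone gene, was at 26.1 ± 4.21 CPM in control and 15.8 ± 1.49 CPM in FLI, a log2 difference of -0.70 (SE 0.16). JUND (ENSBTAG00000052791, chromosome 7, 4912209 to 4913960), a transcription factor of the AP-1 family, was at 47.1 ± 10.4 CPM in control and 28.2 ± 2.68 CPM in FLI, a log2 difference of -0.71 (SE 0.18). CDH26, a cadherin of cell adhesion, was at 3.88 ± 0.995 CPM in control and 1.1 ± 0.997 CPM in FLI. UGT8, which makes galactosylceramide, was at 12.8 ± 3.57 CPM in control and 5.23 ± 3.01 CPM in FLI. KRT80, a keratin, was at 1.61 ± 0.123 CPM in control and 0.760 ± 0.218 CPM in FLI. CRISPLD1 was at 2.83 ± 0.711 CPM in control and 0.837 ± 0.858 CPM in FLI. FLI 4M had the highest FLI level of both CDH26 (2.48 CPM, others 0.262 to 1.04) and CRISPLD1 (2.07 CPM, others 0.0699 to 0.628). All 4 FLI samples lay below all 4 controls for H2BC15, JUND, CDH26 and KRT80, and 3 of 4 did for UGT8 and CRISPLD1.

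**Figure D1:**
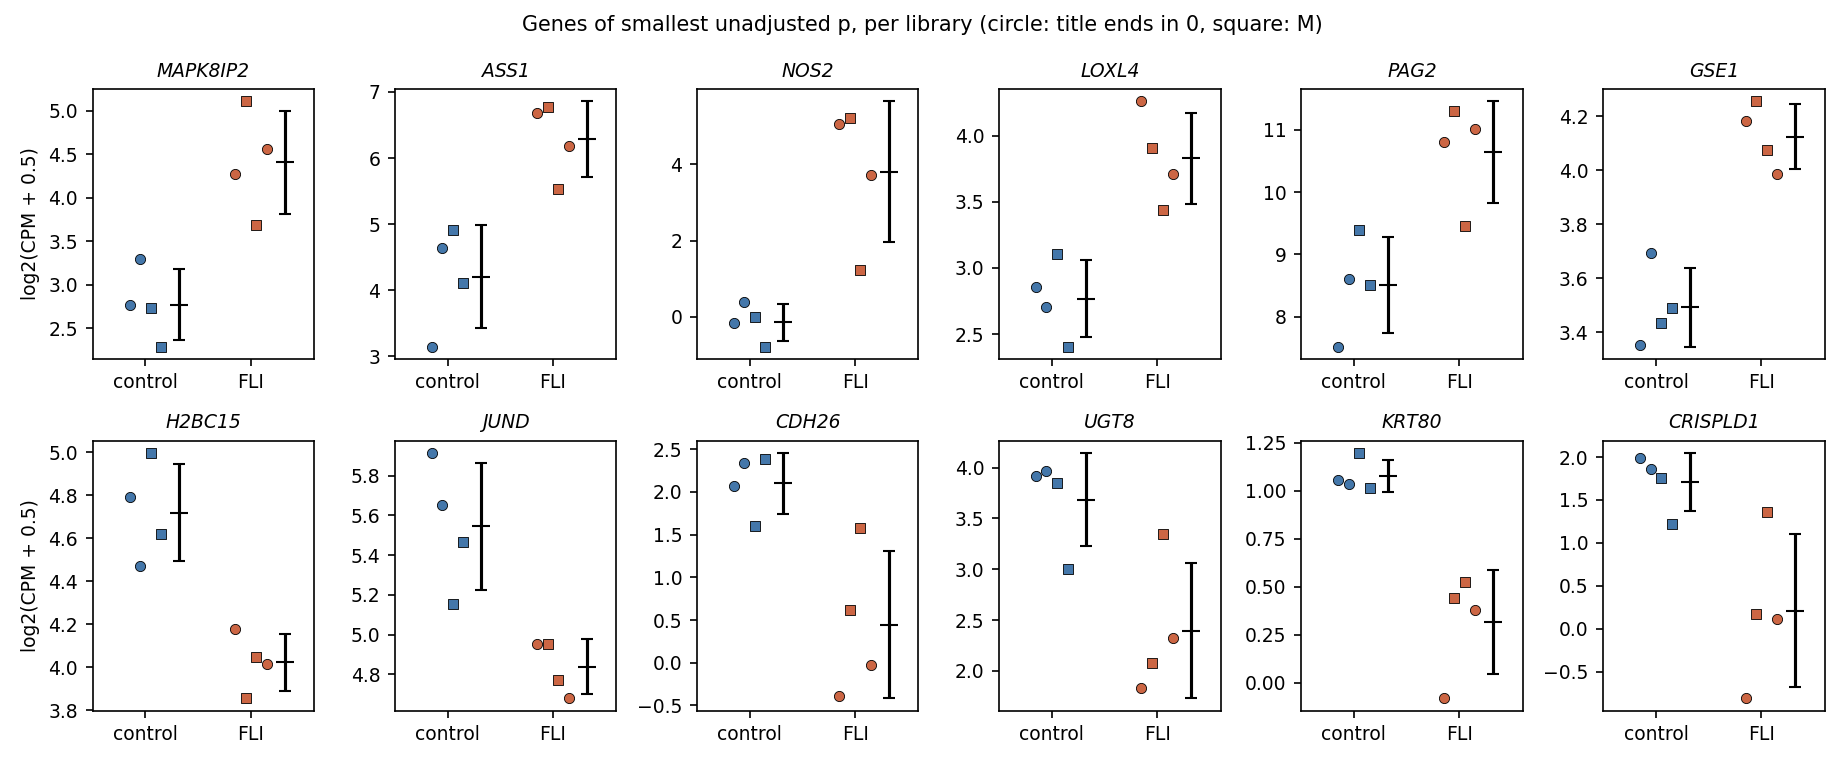
The 6 genes with a symbol of smallest unadjusted p in each direction in the comparison of FLI with control, as log2(CPM + 0.5) in each library, with the mean and SD of each group (n = 4) beside the points. NOS2 lies between 1.83 and 36.5 CPM in the FLI libraries and at no more than 0.802 CPM in the controls; all genes shown have an adjusted p of 0.97.

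Of the tested genes, 338 had an unadjusted p under 0.05 in limma, 225 higher and 113 lower in FLI, where 595 are expected with no effect. The groups did not overlap for 172 genes, 1.45% of those tested, where chance gives 2.86%. The edgeR quasi-likelihood test called 0 genes with 568 at an unadjusted p under 0.05, and limma-voom with quality weights called 0 with 270. DESeq2 called 13 genes (10 higher, 3 lower), an edgeR likelihood ratio test with robust observation weights 33, and the same test without weights 51. No label says that the samples come from separate animals, so each p-value measures only the spread between these samples.

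The authors' deposited table lists 32 genes at an adjusted p under 0.05, 24 higher and 8 lower in FLI. In the authors' deposited table NOS2 has a log2 fold change of 5.58 (adjusted p = 4.43e-08), ASS1 2.0 (adjusted p = 6.79e-05), PAG2 2.26 and MAPK8IP2 1.72. PTGS2, the inducible enzyme of prostaglandin synthesis, has 2.90 in the authors' deposited table (adjusted p = 0.00594). The likelihood ratio test without weights did not call PTGS2. Of these 32 genes, 22 were tested by limma, 21 of them had an unadjusted p under 0.05, and 10 of the 32 had groups that did not overlap. Further genes of the authors' deposited table are named here after their values were seen. CYP19A1, the aromatase of estrogen synthesis, was at 1.99 ± 1.22 CPM in control and 17.4 ± 11.9 CPM in FLI. RNASE1, a secreted ribonuclease, was at 14.4 ± 11.8 CPM in control and 114 ± 96.0 CPM in FLI. PLA2G7, a secreted phospholipase, was at 23.7 ± 24.7 CPM in control and 170 ± 148 CPM in FLI. TBX2, a T-box transcription factor not called without weights, was at 7.22 ± 7.34 CPM in control and 30.7 ± 21.2 CPM in FLI. In FLI 4M these 4 genes stood at 1.26, 17.4, 18.7 and 5.56 CPM, inside the control range for each, and FLI 20 had the highest RNASE1 (237 CPM), PLA2G7 (373.5 CPM) and TBX2 (57.3 CPM). AFP, a secreted protein of yolk sac endoderm, is among the genes lower in FLI, with 4.76 CPM in control 10, 10.6 CPM in control 20 and at most 0.0157 CPM in the other 6 samples. COL1A2, a fibrillar collagen, had 5.62 CPM in control 10 and 1.36 CPM in control 20, and at most 0.172 CPM in the others.

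Of 28 fixed gene lists with at least 5 tested members, camera with a preset correlation of 0.01 called 4 as higher and 2 as lower in FLI. Of the other 22 lists, 17 were called in at least 1 of 21 alternative fits. The list of interferon tau and trophoblast secretory products was called higher: 11 of 11 tested members had a higher mean in FLI, with a mean log2 difference of 1.70 (SE 0.62) and an adjusted p of 3.87e-08 (adjusted p = 0.636 with an estimated correlation). The list mean, in log2(CPM + 0.5), was 6.66 to 8.69 in the controls, 8.35 in FLI 4M and 9.72 to 10.5 in the other FLI samples. FLI 4M thus lay inside the control range. Of the members too low to be tested, SPP1 and PAG1 had a lower mean in FLI and TKDP2 and PAG7 a higher one. PAG2 was the 1 member that passed when adjusted over the list alone, with an adjusted p of 0.0215. TKDP4, a trophoblast Kunitz domain protein, was at 114 ± 91.3 CPM in control and 3776 ± 6721 CPM in FLI, where FLI 20 alone had 13860 CPM and the other FLI samples 224 to 642 CPM. Interferon tau, the conceptus signal for maternal recognition of pregnancy, was at 2156 ± 1412 CPM in control and 4220 ± 1398 CPM in FLI, summed over the 4 copies that the list names (exact two-sided permutation p = 0.0857, adjusted 0.129 over 3 families). Control 10 had 594.5 CPM, and without it the log2 difference of the sum was 0.67 in place of 1.19. FLI 4M had 2149 CPM, inside the control range of 594.5 to 3969 CPM. These are multicopy families, so the values of their single copies are uncertain. How alike the copies are was not measured. The trophectoderm transcription factors had 21 of 28 members higher (adjusted p = 0.0669), and 5 of the 21 alternatives called them higher: library size alone (0.37, adjusted p = 0.00786), no filter (0.43, 0.0336), titles ending in 0 (0.89, 0.00674), without control 20 (0.54, 0.0384) and without control 4M (0.61, 0.0205). DLX5 was at 41.9 ± 21.0 CPM in control and 97.0 ± 42.3 CPM in FLI and TP63 at 3.97 ± 2.24 and 16.5 ± 17.8 CPM. Control 10 had the lowest level of both genes, 11 and 0.737 CPM, and FLI 20 carried the TP63 mean, with 43.0 CPM against 4.88 to 9.23 CPM in the other FLI samples.

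The list of lipid uptake, storage and oxidation was called higher, with 34 of 44 members higher, a mean log2 difference of 0.29 (SE 0.16) and an adjusted p of 0.00243 (adjusted p = 0.636 with an estimated correlation). MGLL, which releases fatty acids from monoacylglycerol, was at 119 ± 33.0 CPM in control and 188 ± 40.2 CPM in FLI. LPL, which frees fatty acids from lipoproteins, went the other way at 2.66 ± 1.86 and 0.732 ± 0.760 CPM, with 1.83 CPM in FLI 4M and 0.0874 to 0.513 CPM in the other FLI samples. Oxidative phosphorylation genes were called higher with a mean difference of 0.08 (SE 0.07), 43 of 52 members higher and an adjusted p of 0.00331 (adjusted p = 0.79 with an estimated correlation), but with library size alone as the scaling their mean difference was -0.02. SDHC, a subunit of complex II, was at 76.0 ± 14.2 CPM in control and 105 ± 11.1 CPM in FLI, and NDUFS7, of complex I, at 60.6 ± 4.57 and 71.2 ± 9.04 CPM. Cytosolic ribosomal protein genes were called higher with a mean difference of 0.11, less than its SE of 0.13, 56 of 57 members higher and an adjusted p of 0.00119 (adjusted p = 0.79 with an estimated correlation). Of the members of these 3 lists 0 passed singly. RPL35 was at 708 ± 64.2 CPM in control and 817 ± 115 CPM in FLI.

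The epiblast and embryonic disc list shifted down, with 15 of 17 members lower, a mean log2 difference of -0.51 (SE 0.33) and an adjusted p of 0.00119 (adjusted p = 0.79 with an estimated correlation). DNMT3B, a de novo DNA methyltransferase and the member of highest level, was at 188 ± 45.9 CPM in control and 145 ± 19.5 CPM in FLI. TRIM71 was higher, at 15.1 ± 3.10 CPM in control and 21.5 ± 2.88 CPM in FLI. DNMT3B stood at 137 and 136 CPM in FLI 20 and FLI 50, and TRIM71 at 22.3 and 21.3 CPM. Some members were low in these samples: POU5F1 stood at 1.42 and 1.01 CPM there, against 10.2 and 17.4 CPM in FLI 3M and FLI 4M and 4.80 to 32.7 CPM in the controls. NANOG, named after its values were seen, stood at 0.0175 and 0.0592 CPM in FLI 20 and FLI 50, 1.84 and 4.13 CPM in FLI 3M and FLI 4M, and 0.903 to 5.66 CPM in the controls. Among streak and mesoderm genes 6 of 10 were lower (adjusted p = 0.383), with calls as lower without a filter (-0.41, adjusted p = 0.0031) and among titles ending in 0 (-0.70, 0.023). EOMES, a T-box factor of the streak, was at 2.62 ± 1.76 CPM in control and 0.937 ± 1.10 CPM in FLI. Among titles ending in M, POU5F1 and EOMES were higher in FLI, by a log2 of 0.70 and 0.49. EOMES had 0 reads in FLI 20, which allows a level of up to 0.0262 CPM by counting error. SNAI1, a factor of epithelial to mesenchymal transition, was at 7.57 ± 1.03 and 6.26 ± 1.44 CPM. Amino acid transport genes shifted down as well, with 19 of 22 members lower, a mean log2 difference of -0.34 (SE 0.33) and an adjusted p of 0.00765 (adjusted p = 0.79 with an estimated correlation). SLC1A5, a glutamine transporter, was at 132 ± 41.1 CPM in control and 82.2 ± 31.1 CPM in FLI, and SLC7A2, a carrier of arginine and lysine, at 8.70 ± 7.31 and 3.03 ± 2.02 CPM. SLC7A2 was highest in control 10, at 19.6 CPM.

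**Figure D2:**
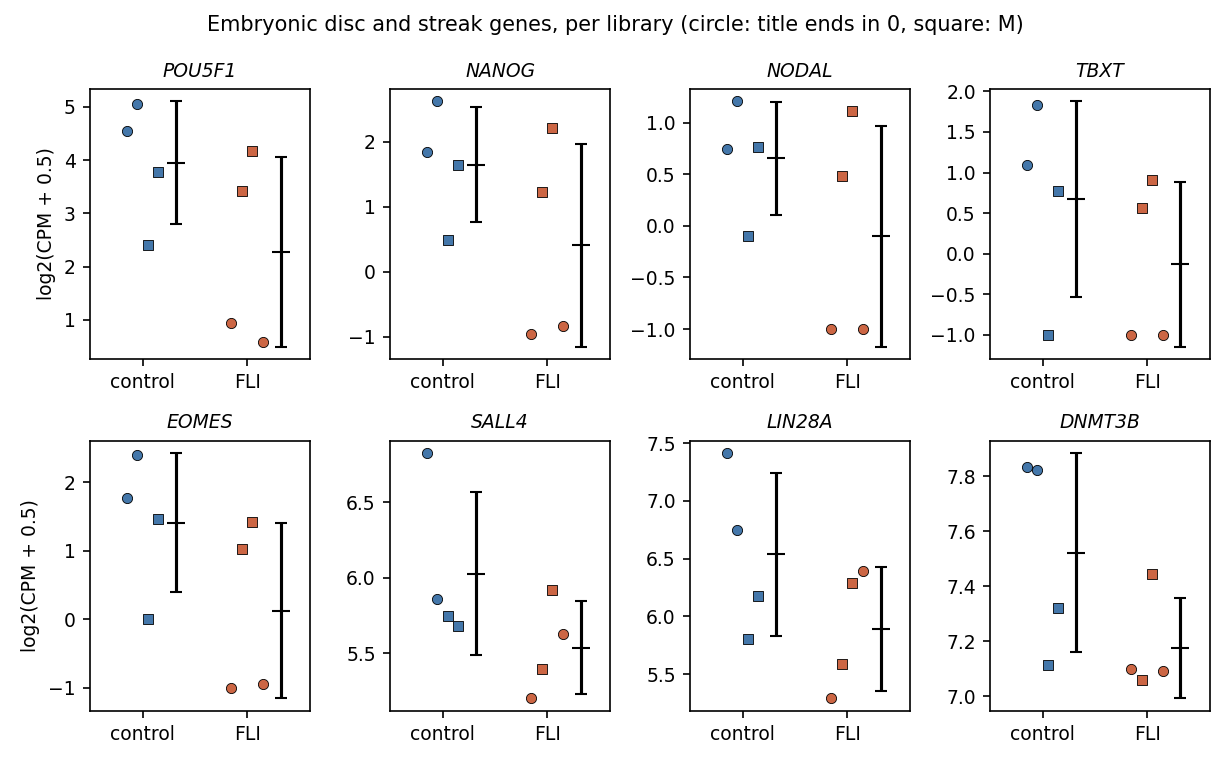
Embryonic disc and streak genes, as log2(CPM + 0.5) in each library, with the mean and SD of each group (n = 4) beside the points. POU5F1 lies at 1.42 and 1.01 CPM in FLI 20 and FLI 50 and at 10.2 and 17.4 CPM in FLI 3M and FLI 4M; NANOG, NODAL, TBXT, SALL4 and LIN28A were chosen for the plot after their values were seen.

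The secretory call was the 1 call kept in all alternatives run with the preset correlation, with mean differences from 0.97 among samples with titles ending in M (adjusted p = 0.000113) to 2.42 among those ending in 0 (adjusted p = 2.49e-06). The lipid call was lost without control 3M (adjusted p = 0.0678) and among samples with titles ending in 0 (adjusted p = 0.164). The epiblast difference was -0.32 without FLI 20 (adjusted p = 0.0317), -1.21 among titles ending in 0 and 0.19 among those ending in M (adjusted p = 0.148). Amino acid transport lost its call without control 10 (-0.10, adjusted p = 0.544), without control 20 (-0.26, 0.0609), without FLI 3M (-0.23, 0.105), with the epiblast list's mean as a covariate (-0.01, 0.841), with library size alone (-0.44, 0.0683) and among titles ending in M (0.07, 0.175). Oxidative phosphorylation lost its call without control 10 (0.03, adjusted p = 0.315), without FLI 3M (0.04, 0.277), with the covariate (0.04, 0.184), with library size alone (-0.02, 0.375) and among titles ending in M (0.05, 0.175). Ribosomal proteins lost theirs without control 10 (0.04, adjusted p = 0.315), without FLI 3M (0.04, 0.405), with the covariate (0.02, 0.791), with library size alone (0.01, 0.0669) and among titles ending in M (0.07, 0.148). The largest differences were -0.75 for amino acid transport among titles ending in 0 and, without control 3M, 0.12 for oxidative phosphorylation and 0.20 for ribosomal proteins. With the title number as a block on 6 samples, the secretory (1.25, adjusted p = 0.000442), lipid (0.0294), ribosomal (0.000442) and epiblast (0.0368) calls were kept, and amino acid transport (-0.18, 0.318) and oxidative phosphorylation (0.05, 0.0857) lost theirs. The block added cholesterol biosynthesis (adjusted p = 3.93e-05), glucose transport (0.0155) and hypoblast genes (0.0368) as higher and cell cycle genes (0.0332) as lower, and with the block and an estimated correlation the smallest adjusted p was 0.739. Of the 28 lists, 0 passed fry (smallest adjusted p = 0.891, or 0.745 for changes in either direction) and 0 passed the exact two-sided permutation test of list means after adjustment (smallest p = 0.0571, adjusted 0.914), where the smallest p that the design allows is 0.029 before adjustment.

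**Figure D3:**
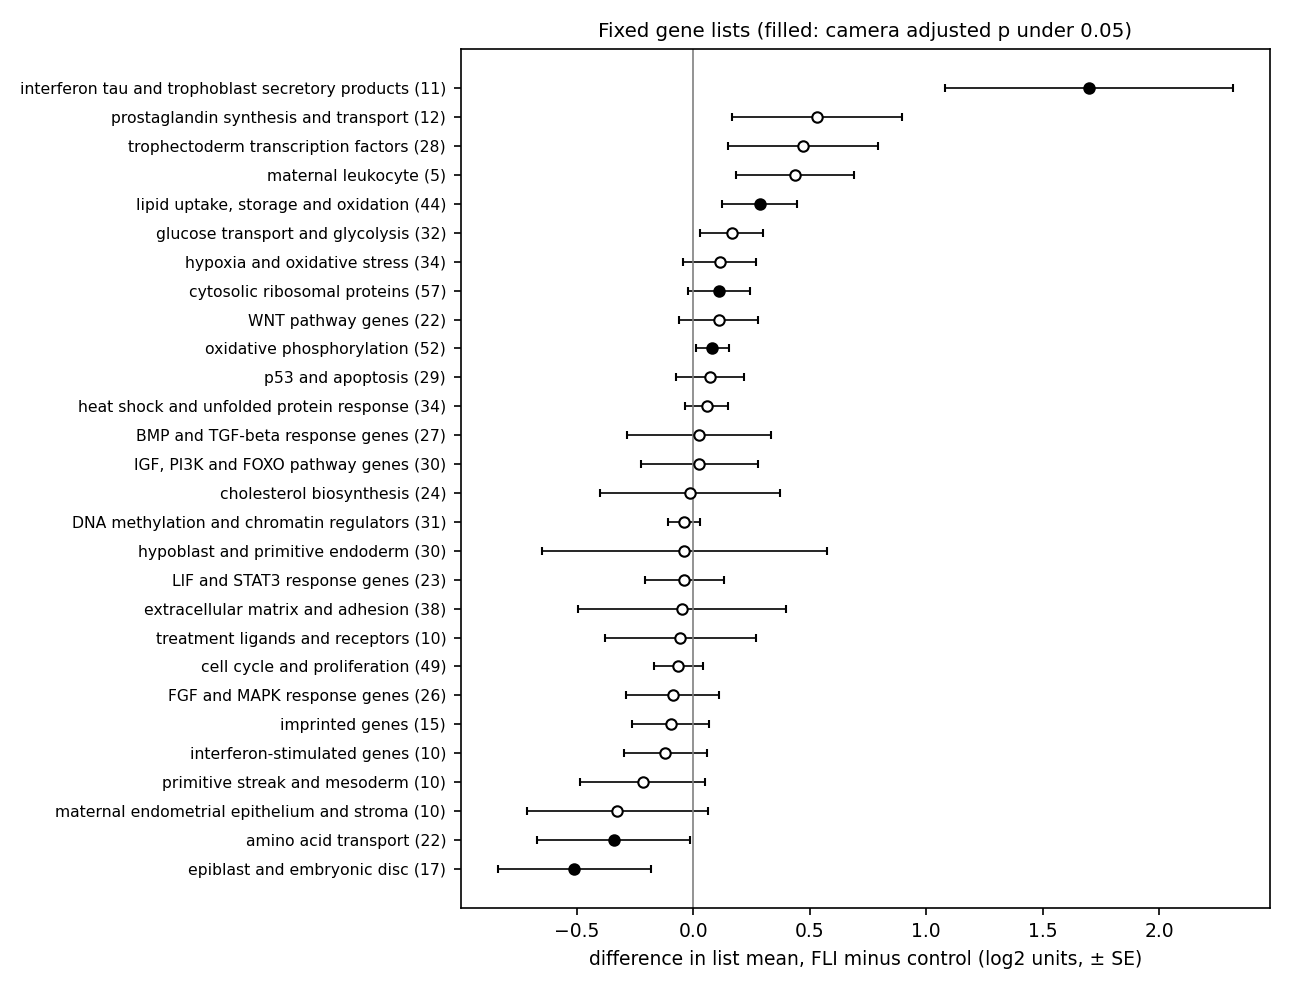
Difference in list mean between FLI and control in log2 units with its SE over 4 and 4 libraries, with the number of tested members after each name. Filled points mark the 6 lists called by camera with the preset correlation, of which 0 were called with an estimated correlation; the oxidative phosphorylation difference of 0.08 was -0.02 with library size alone.

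No tested receptor for the added factors passed: 6 of 10 tested members of the ligand and receptor list were lower and 4 higher (adjusted p = 0.656). The list has 14 symbols, and LIFR, FGF2, LIF and IGF1 were not among the tested members. FGFR2, a receptor for fibroblast growth factors, was at 23.0 ± 11.5 CPM in control and 41.8 ± 35.5 CPM in FLI, and FGFR1 at 44.1 ± 36.5 and 22.5 ± 5.92 CPM. FLI 20 carried the FGFR2 mean, with 94.7 CPM against 18.8 to 28.3 CPM in the other FLI samples. FGFR3 was at 62.1 ± 43.9 and 71.3 ± 45.7 CPM, FGFR4 at 4.08 ± 3.03 and 2.08 ± 0.688 CPM and KLB, a co-receptor of the family, at 218 ± 194 and 140 ± 55.5 CPM. IGF1R, the receptor of IGF1, was at 3.39 ± 1.39 CPM in control and 9.04 ± 10.1 CPM in FLI, of which FLI 20 had 23.9 CPM. The related genes IGF2R (167 ± 48.7 and 143 ± 45.9 CPM), INSR (1.23 ± 0.791 and 0.978 ± 0.919 CPM) and IGF2 (15.3 ± 17.0 and 6.35 ± 1.93 CPM) overlapped between the groups. Control 10 had the highest FGFR1 (90.7 CPM), FGFR4 (8.53 CPM), KLB (484 CPM) and IGF2 (40.2 CPM). IL6ST, the signalling subunit of the LIF receptor, was at 22.7 ± 3.93 and 31.3 ± 20.2 CPM, with 61.1 CPM in FLI 20.

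Response genes of the 3 pathways were not called by camera with all 8 samples. FGF and MAPK response genes were called lower without control 3M (-0.24, adjusted p = 0.0181) and LIF and STAT3 response genes without both control 10 and FLI 20 (-0.15, adjusted p = 0.0287). Among FGF and MAPK response genes 18 of 26 were lower (adjusted p = 0.22), with SPRY2, a feedback inhibitor of the pathway, at 7.57 ± 2.16 CPM in control and 5.43 ± 1.58 CPM in FLI and ETV4 at 2.81 ± 1.5 and 3.83 ± 0.626 CPM. Among LIF and STAT3 response genes 12 of 23 were higher (adjusted p = 0.646), and the signs differed: the median log2 difference was 0.14, the mean -0.04, and camera's direction was down. JAK2, the kinase upstream of STAT3, was at 11.3 ± 3.27 and 7.56 ± 1.65 CPM and MCL1, a survival factor, at 233 ± 36.6 and 186 ± 23.8 CPM. Among IGF, PI3K and FOXO genes 15 of 30 were higher (adjusted p = 0.646), with a median of -0.01, a mean of 0.03 and camera's direction down. GRB10, an imprinted adaptor that restrains insulin and IGF signalling, was at 27.4 ± 3.18 CPM in control and 20.8 ± 1.22 CPM in FLI, with all 4 FLI samples below all controls. IGF2BP2, an RNA-binding protein, was at 2.48 ± 1.28 and 0.739 ± 0.628 CPM, with 1.65 CPM in FLI 4M.

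Among metabolic and signalling lists that did not pass, glucose transport and glycolysis had 22 of 32 members higher (adjusted p = 0.0669), with LDHA, the lactate-forming enzyme, at 302 ± 47.4 CPM in control and 439 ± 54.2 CPM in FLI and ALDOC at 9.24 ± 1.81 and 15.0 ± 6.49 CPM. Besides the block, 6 alternatives called this list higher: no filter (0.16, adjusted p = 0.0277), the epiblast covariate (0.23, 7.04e-05), titles ending in M (0.27, 3.22e-05), without control 10 (0.24, 0.00169), without control 20 (0.22, 0.0384) and without both control 10 and FLI 20 (0.19, 7.61e-05). All 4 FLI samples exceeded all controls for LDHA. Prostaglandin synthesis and transport had 7 of 12 members higher (adjusted p = 0.22) and was called higher with the epiblast covariate (0.59, adjusted p = 0.0258), among titles ending in M (0.84, 0.00141), without control 20 (0.81, 0.0206) and without both control 10 and FLI 20 (0.56, 0.0381). PTGS2 was at 1044 ± 1380 CPM in control, where control 20 had 3096 CPM, and at 3651 ± 1850 CPM in FLI, and AKR1B1, a prostaglandin F synthase, at 692 ± 154 and 1690 ± 1305 CPM. FLI 20 carried the AKR1B1 mean, with 3633 CPM against 820 to 1182 CPM in the other FLI samples. Cholesterol biosynthesis had 13 of 24 lower (adjusted p = 0.811), with MVK at 36.6 ± 11.4 and 47.7 ± 8.85 CPM and SREBF2 at 217 ± 47.0 and 281 ± 80.1 CPM. Cholesterol biosynthesis was called higher among titles ending in M (0.29, adjusted p = 3.5e-07) and without control 10 (0.27, 0.00169), and lower among titles ending in 0 (-0.32, 0.00833). Hypoxia and oxidative stress genes had 22 of 34 higher (adjusted p = 0.491), with HMOX1, a heme-degrading enzyme, at 23.9 ± 8.16 and 90.6 ± 86.2 CPM and VEGFA at 87.2 ± 33.5 and 141 ± 56.3 CPM. The list was called higher among titles ending in M (0.22, adjusted p = 0.00147) and without both control 10 and FLI 20 (0.19, 0.00325). HMOX1 stood at 214 CPM in FLI 20 and at 28.7 to 85.5 CPM in the other FLI samples. BMP and TGF-beta response genes had 15 of 27 lower (adjusted p = 0.692), with a median of -0.09, a mean of 0.03 and camera's direction down. Among titles ending in M the BMP list (0.30, adjusted p = 0.0136) and the WNT list (0.29, 0.0147) were called higher. CCN1 was at 149 ± 64.8 and 80.7 ± 28.4 CPM and PMEPA1 at 11.7 ± 6.97 and 24.6 ± 8.57 CPM. WNT pathway genes had 12 of 22 higher (adjusted p = 0.692), with the target gene AXIN2 at 7.25 ± 0.648 and 4.05 ± 2.71 CPM and RSPO3, a WNT agonist, at 6.76 ± 2.42 and 2.71 ± 1.98 CPM.

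Cell cycle genes had 31 of 49 members lower (adjusted p = 0.164), with RRM2, a ribonucleotide reductase subunit, at 540 ± 75.3 CPM in control and 395 ± 92.9 CPM in FLI and CCNE2 at 23.8 ± 5.51 and 17.7 ± 3.43 CPM. Besides the block, they were called lower without control 10 (-0.11, adjusted p = 0.0124), without control 20 (-0.08, 0.0384) and without FLI 4M (-0.12, 0.024). DNA methylation and chromatin regulators had 23 of 31 lower (adjusted p = 0.164), with HDAC2 at 59.6 ± 2.60 and 50.1 ± 5.86 CPM and DNMT1 at 84.3 ± 11.9 and 67.6 ± 12.6 CPM, and were called lower without control 20 (-0.06, adjusted p = 0.0384). Imprinted genes had 9 of 15 lower (adjusted p = 0.22), with PEG3 at 54.6 ± 7.96 and 91.2 ± 41.8 CPM (152 CPM in FLI 20, 56.9 to 80.7 CPM in the other FLI samples), and were called lower among titles ending in 0 (-0.38, adjusted p = 0.0296). The p53 and apoptosis list had 16 of 29 higher (adjusted p = 0.692), with SESN2 at 36.1 ± 10.6 and 59.2 ± 16.9 CPM and BCL2L1 at 90.7 ± 25.7 and 65.3 ± 8.15 CPM. The heat shock and unfolded protein list had 19 of 34 higher (adjusted p = 0.646), with CALR, a chaperone of the endoplasmic reticulum, at 2052 ± 493 and 2831 ± 215 CPM and DNAJA1 at 236 ± 31.4 and 191 ± 27.3 CPM. Interferon-stimulated genes had 6 of 10 lower (adjusted p = 0.646), with HERC5 at 14.8 ± 5.02 and 8.15 ± 4.0 CPM and USP18 at 8.94 ± 2.99 and 12.5 ± 2.52 CPM, and were called lower without a filter (-0.34, adjusted p = 0.00226). Extracellular matrix and adhesion genes had 22 of 38 lower (adjusted p = 0.646), with ITGB6 at 1.47 ± 0.839 and 0.386 ± 0.416 CPM (1.01 CPM in FLI 4M) and ITGA6 at 165 ± 65.0 and 308 ± 185 CPM (572 CPM in FLI 20). They were called lower among titles ending in 0 (-0.38, adjusted p = 0.000462) and without control 3M (-0.30, 0.0459), and higher among titles ending in M (0.29, 0.000113) and without control 10 (0.26, 0.0183).

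Markers of other cell types were not called by camera at the settings used, but 2 of their lists were in alternatives. Hypoblast and primitive endoderm genes had 17 of 30 members lower (adjusted p = 0.491), with PDGFRA at 19.96 ± 3.51 CPM in control and 10.03 ± 7.91 CPM in FLI (21.7 CPM in FLI 4M) and FOXA1 at 28.0 ± 4.02 and 37.6 ± 9.26 CPM. They were called lower among titles ending in 0 (-0.57, adjusted p = 0.000115), without control 3M (-0.42, 0.00742) and without control 4M (-0.28, 0.0402), and higher among titles ending in M (0.49, 3.5e-07) and with the block. Markers of maternal leukocytes had 5 of 5 tested members higher (adjusted p = 0.491), with CD14 at 2.14 ± 2.07 and 4.82 ± 4.53 CPM (11.3 CPM in FLI 20) and GZMB at 3.37 ± 5.90 and 4.37 ± 5.0 CPM. GZMB stood at 12.2 CPM in control 10 and 11.4 CPM in FLI 20, and at 0.0448 to 4.35 CPM in the other samples. CD8A, FCER1G and CD68 differed by a log2 of only 0.02, 0.05 and 0.07. Leukocyte markers too low to be tested mostly went the other way. CD74 was at 2.23 CPM in control and 0.436 CPM in FLI, and LYZ1 at 1.23 and 0.122 CPM. CD74 stood at 4.46 and 3.43 CPM in control 10 and control 20, and at 0.284 and 0.756 CPM in control 3M and control 4M. Control 10 carried the LYZ1 mean, with 4.49 CPM against at most 0.401 CPM in the other controls. BOLA-DRA, S100A12 and CD3D were also lower in FLI, CXCR4 hardly differed (0.2 and 0.192 CPM), and JCHAIN was higher (0.682 and 0.762 CPM). Markers of maternal endometrium had 8 of 10 lower (adjusted p = 0.0774), with PAX8 at 1.72 ± 0.568 and 1.04 ± 0.313 CPM and complement C3 at 6.15 ± 2.35 and 4.14 ± 2.76 CPM. They were called lower without a filter (-0.32, adjusted p = 0.0336), among titles ending in 0 (-0.88, 0.000381), without control 3M (-0.55, 0.0149) and without control 4M (-0.51, 0.0174). TDGF1, the endometrial list's member of highest level, is also on the epiblast list and was at 122 ± 69.5 and 84.4 ± 27.1 CPM. FOXA2 (11.47 ± 8.48 and 7.56 ± 1.54 CPM) and SOX17 (30.93 ± 18.85 and 20.01 ± 3.71 CPM) are also on the hypoblast list. The endometrial list therefore cannot be read as maternal tissue alone. Of the blood and erythroid list 1 gene was tested, too few for camera: ALAS2, of heme synthesis, was at 66.6 CPM in FLI 20 and 0.553 to 4.06 CPM in the other samples.

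Leaving out 1 sample moved the log2 difference of 42 of the 77 named genes by over 1.5 times or turned it, toward or past 0 for 41 of them. Without FLI 20 it fell from 3.34 to 2.04 for TKDP4, 1.67 to 1.05 for TP63, 1.48 to 0.91 for HMOX1, 1.06 to 0.60 for AKR1B1, 0.83 to 0.47 for ITGA6, 0.82 to 0.18 for IGF1R, 0.71 to 0.22 for FGFR2 and 0.65 to 0.37 for PEG3. It also fell from 0.60 to 0.34 for ALDOC, 0.35 to 0.18 for SREBF2, 0.20 to 0.12 for RPL35, 1.08 to 0.57 for CD14 and 0.97 to 0.33 for GZMB. Among genes lower in FLI it went without FLI 20 from -0.91 to -0.56 for HERC5, -0.61 to -0.38 for C3, -0.47 to -0.31 for RRM2, -0.37 to -0.12 for TDGF1 and -0.33 to -0.19 for DNMT1. Without control 10 it went from 1.33 to 0.78 for DLX5, 1.25 to 0.68 for PMEPA1, 1.08 to 0.54 for CD14, 0.83 to 0.52 for ITGA6, 0.71 to 0.32 for FGFR2, 0.50 to 0.30 for USP18 and 0.50 to 0.31 for CALR. Without control 10 it also went from -1.30 to -0.83 for SLC7A2, -0.67 to -0.28 for FGFR4, -0.67 to -0.02 for IGF2, -0.44 to -0.26 for BCL2L1, -0.41 to -0.27 for CCNE2 and -0.37 to -0.10 for TDGF1. POU5F1 went from -1.67 to -1.11 and SPRY2 from -0.44 to -0.26 without FLI 50, VEGFA from 0.67 to 0.44 without FLI 3M, and SNAI1 from -0.27 to -0.17 without FLI 4M. ETV4 went from 0.48 to 0.28 and MVK from 0.41 to 0.22 without control 3M, while FOXA1 went from 0.39 to 0.59 without FLI 4M and ETV4 to 0.75 without control 20. Some genes named above also moved away from 0 without another sample. GZMB reached 1.97 without control 10 and 1.56 without FLI 4M, where IGF1R reached 1.32 and C3 -0.96. IGF2 reached -1.14 without control 4M and TDGF1 -0.81 without control 3M.

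Whole transcriptomes were not separated by treatment more than by other splits of the samples. Treatment took 12.8% of the sum of squares of the 500 most variable genes, with an exact permutation p of 0.457 over 35 splits, where the smallest possible p is 0.029. The first principal component held 46.2% of the variance and set control 10 apart, with a score of -81.2. This component also followed the last character of the title: samples ending in 0 scored -81.2 to -3.64 and those ending in M 24.5 to 42.9. The second component held 25.2% and set FLI 20 apart, with a score of -66.9. Control 10 also had the lowest median correlation with the other libraries (0.884), followed by FLI 20 (0.921), where the other samples had 0.954 to 0.968. Without both of these samples the secretory list's mean log2 difference was 0.99 (adjusted p = 2.17e-08) and the lipid list's was 0.26 (adjusted p = 9.51e-05). Without both samples the adjusted p was 0.182 for the epiblast list, 0.768 for amino acid transport, 0.154 for oxidative phosphorylation and 0.521 for ribosomal proteins, and limma called 0 genes with 172 at an unadjusted p under 0.05.

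**Figure D4:**
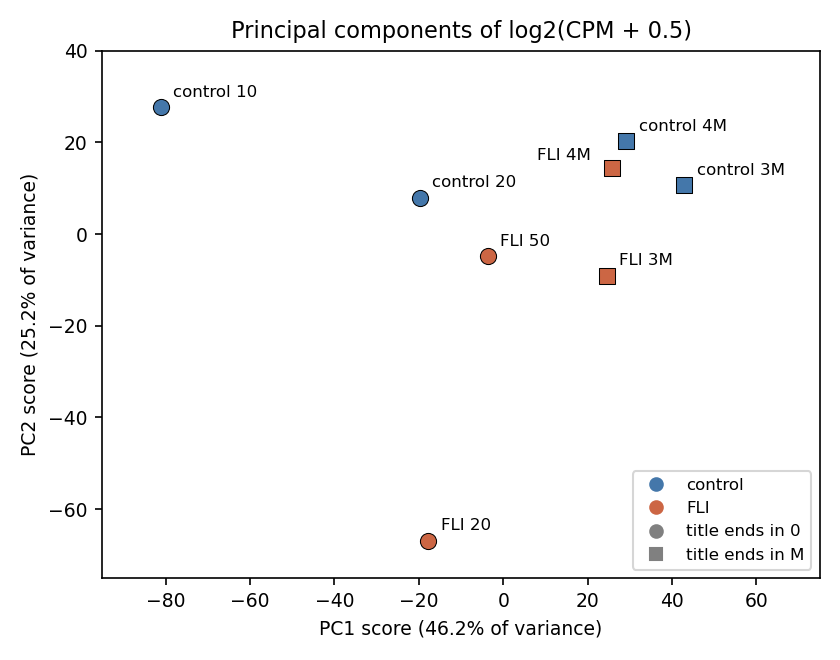
Scores of the 8 libraries on the first and second principal components of log2(CPM + 0.5), with the percent of variance on each axis, coloured by group and shaped by the last character of the title. Control 10 lies at -81.2 on the first component and FLI 20 at -66.9 on the second. Samples ending in 0 lie at -81.2 to -3.64 on the first component and those ending in M at 24.5 to 42.9.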

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

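The likelihood ratio tests of genes were added after the data were seen, and the tests of overlapping groups, of control 10 in the secretory list and of the trophoblast share were chosen after the result was seen.

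Among 212 groups of 4 samples (named genes and lists in control or FLI), 11 held a sample far from its 3 group mates, where chance gives 10.6. Control 10 was that sample in 4 groups, FLI 4M in 3 and control 20 in 2. All values here are log2(CPM + 0.5). In control 10, DLX5 was 3.521 against 5.603 to 5.866, TP63 was 0.307 against 2.228 to 2.612, GRB10 was 5.028 against 4.697 to 4.738, and the mean of the trophectoderm transcription factors was 4.171 against 5.296 to 5.518. In control 20, VEGFA was 7.108 against 6.139 to 6.155 and the mean of the lipid list was 5.996 against 5.457 to 5.461. In control 4M, UGT8 was 3.002 against 3.846 to 3.971. In FLI 4M, DNMT3B was 7.446 against 7.058 to 7.099, FOXA1 was 4.6 against 5.372 to 5.449, and ITGB6 was 0.594 against -0.623 to -0.477. In FLI 3M, MGLL was 7.956 against 7.347 to 7.45.

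Limma called 0 genes, a number that all 35 of the 35 ways to split the samples into 4 and 4 reach (highest other 3), so this count says nothing about chance. For the likelihood ratio test with robust weights chance cannot be excluded: 18 of the 35 splits gave at least its 33 genes, with 1659 for the split by the last character of the title, and 4 of the 8 splits that part all 3 pairs of equal number did (highest other 114). Against the weights as the cause of most calls, 25 of the 33 genes were also called without weights, but PTGS2 and TBX2 were not. Of the 33 genes, 17 had at least 1 sample weighted under 0.5. Control 20 was so weighted for 10 genes and FLI 20 for 7. The groups did not overlap for 10 of the 33, which fits calls that may rest on a few samples. For camera with the preset correlation, 24 of the 35 splits gave at least the 6 lists (highest other 12), and 4 of the 8 splits that part all pairs did (highest other 11), so chance cannot be excluded there either.

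The higher trophoblast secretory products in FLI have several candidate explanations. Without control 10 the mean log2 difference was 1.2966, against 1.70 with all samples. This argues against that sample alone as the cause of the list's mean difference. Camera's call was kept (adjusted p = 2.39e-06, within a range of 3.46e-11 to 0.636 over the alternatives). With the preset correlation 24 of the 35 splits gave at least 6 lists, so the kept call cannot decide. Without control 10 the difference of the interferon tau sum went from 1.19 to 0.67. That of the PAG sum went from 0.98 to 0.48 and that of the Kunitz sum from 1.81 to 1.51. A larger trophoblast share stays open: the upper 95% limit for the trophectoderm transcription factors was 1.2616, below the secretory difference of 1.70 (0.19 to 3.21), and the secretory products rose by 1.23 more than the factors (0.13 to 2.32), but the exact permutation p of 0.0571 for this contrast, required after its value was seen, misses 0.05, and 5 of 21 alternatives called the factors higher. Reads moved between copies of a family stay open: the smallest difference of the 3 family sums was 0.9792, for the PAG genes (0.48 without control 10), and its 95% interval of -0.87 to 2.83 includes 0. The sums hold only copies that the list names, so reads assigned to any unnamed copy were not counted. An effect of the added factors stays open as well, as the biological explanation that the design names.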

How the results depend on the processing

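The edgeR fits, the fit without both control 10 and FLI 20, the fits within the last character of the title and the planned log2 CPM scale were added after seeing the data; the other alternatives were planned. Of 25 alternative fits of genes, those other than 3 called 0 genes, as limma did (338 at unadjusted p under 0.05), with 54 (epiblast covariate) to 806 (block) at unadjusted p under 0.05. The exceptions were DESeq2 with 13 genes (10 higher, 3 lower), the likelihood ratio test with robust weights with 33 (25 and 8) and without weights with 51 (40 and 11); the cause was not tested. The smallest adjusted p of limma reached 0.0794 without FLI 4M, within a range of 0.0794 to 1 over the limma fits. With the title number as a replicate block limma called 0 genes (806 at unadjusted p under 0.05), and besides the list calls given with the results it changed no other call. The stricter planned filter equals the one used and tests nothing, and the epiblast list was not tested with its own mean as a covariate.

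Camera called 6 lists, and 11 without a filter, 0 with an estimated correlation, 12 among titles ending in 0 and 10 among those ending in M; leaving out 1 sample gave 3 (without FLI 3M) to 10 (without control 20). Samples left out mean fewer samples tested, and the cause was otherwise not tested. Group separation stayed between 11.01% (without FLI 20) and 19.02% (without FLI 4M), with exact permutation p values of 0.314 to 0.700. With library size alone the oxidative phosphorylation difference was -0.0187 and the median of all genes moved to -0.09. Among titles ending in M the epiblast difference was 0.1885 and that of amino acid transport 0.0656; the causes were not tested.

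Of 77 named genes, 61 kept their direction in all alternatives. The log2 differences that turned, none past the threshold and of untested cause, were these. With limma-voom, IGF2R was 0.0008, IL6ST -0.0063, KLB 0.0917 and ALAS2 -0.5113, and with robust weights ALAS2 was -0.1435. With the block KLB was 0.0979. With the epiblast covariate, IGF2R was 0.1711, IL6ST -0.0214, FGFR1 0.3355, KLB 0.2943, ALAS2 -0.1924 and TDGF1 0.3934. Without both control 10 and FLI 20, FGFR2 was -0.1775, IGF2R 0.172, IL6ST -0.1513, FGFR1 0.0649, KLB 0.2395, ALAS2 -0.7783 and TDGF1 0.1435. Among titles ending in M, POU5F1 was 0.6958, DNMT3B 0.0353, EOMES 0.4924, USP18 -0.0263, ITGA6 -0.1702, FGFR2 -0.2532, IGF2 0.0594, IGF2R 0.2223, IL6ST -0.1827, INSR 0.0615, FGFR1 0.561, KLB 0.4423, ALAS2 -0.257, CD14 -0.173 and TDGF1 0.6336. Leaving out 1 sample gave ranges of -0.4076 to 0.0028 for IGF2R, -0.0872 to 0.5213 for IL6ST, -0.7176 to 0.0179 for INSR, -1.1731 to 0.0415 for FGFR1, -0.1097 to 0.6855 for FGFR3, -0.7749 to 0.3185 for KLB and -0.5932 to 1.405 for ALAS2.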

Other observations

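The comparison by the last character of the title, and the tests of trophoblast share and depth for it, were chosen after the result was seen; the tests of control 10 and of a batch were written before.

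Apart from treatment, samples differed by the last character of their titles, 0 or M, with 2 control and 2 FLI samples on each side. Fibrinogen beta, FGB, a secreted plasma protein of endoderm and liver, was at 24.01 ± 13.6 CPM in the 4 samples ending in 0 and 0.576 ± 0.491 CPM in the 4 ending in M. Its log2 difference was 4.48 (SE 0.31), and it was the 1 gene with a limma adjusted p under 0.05 (0.00883) with treatment in the model, where the split by title without treatment in the model gave 3. At an adjusted p under 0.10 there were 590 genes, 456 of them higher in 0. Camera called 7 of 28 lists as higher and 3 as lower in 0, with 0 called with an estimated correlation and a smallest adjusted permutation p of 0.0889. Hypoblast and primitive endoderm genes were higher in 0 by a mean log2 of 1.34 (95% confidence interval 0.69 to 2.0). Camera gave this list an adjusted p of 1.61e-09 with the preset correlation (adjusted p = 0.382 with an estimated correlation). APOA1, an apolipoprotein of visceral endoderm named after its values were seen, stood at 6183, 2702, 2181 and 2108 CPM in control 10, control 20, FLI 20 and FLI 50 and at 437 to 1109 CPM in the samples ending in M. Genes of the extracellular matrix were higher in 0 by 1.0 (adjusted p = 2.43e-09, and adjusted p = 0.382 with an estimated correlation), as was cholesterol biosynthesis by 0.78 (adjusted p = 1.7e-09, and 0.382 with an estimated correlation). Lower in 0 were ribosomal proteins (-0.21, adjusted p = 6.28e-06), oxidative phosphorylation (-0.13, 0.000831) and cell cycle genes (-0.21, 0.00161), with adjusted p = 0.576, 0.576 and 0.382 with an estimated correlation. Also higher were amino acid transport (0.55, adjusted p = 0.000745, and 0.501 with an estimated correlation), BMP and TGF-beta response genes (0.62, 0.000331, and 0.382), hypoxia genes (0.33, 0.0427, and 0.41) and treatment ligands and receptors (0.70, 0.0276, and 0.382). The epiblast list differed by -0.02 (95% confidence interval -0.97 to 0.93).

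In the streak and mesoderm list, 3 genes chosen after their values were seen stood highest in control 10 and control 20. KDR, a receptor of endothelial precursors, was at 15.9 and 7.02 CPM there and at 0.105 to 0.943 CPM in the other 6 samples. APLNR, the apelin receptor, was at 6.26 and 2.73 CPM and at 0.0224 to 0.416 CPM in the others, and FOXF1, a factor of splanchnic mesoderm, was at 4.01 and 2.02 CPM and at 0.0823 to 0.246 CPM in the others. Other members did not: PDGFRB was highest in FLI 20 (3.57 CPM, against 2.87 and 1.26 CPM in control 10 and control 20), as was TBX3 (95.7 CPM), and ISL1 was highest in control 4M (3.97 CPM).

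The hypoblast difference between titles may come from the tissue that each conceptus-half held, a hypothesis formed on these samples. Without control 10 it was 1.1702, which argues against that sample alone as the cause. The upper 95% limit of the epiblast list was 0.9345, below the hypoblast difference, and hypoblast minus epiblast differed by 1.36 (0.59 to 2.14, exact permutation p = 0.0286, the smallest possible). Epiblast genes thus did not rise with hypoblast genes on average. This cannot decide on a lower trophoblast share, since the epiblast list varied among samples ending in 0. Its mean log2 level was 4.37 in control 10 and control 20, 2.95 in FLI 20 and 3.36 in FLI 50. The trophectoderm transcription factors differed by -0.305 between 0 and M (exact permutation p = 0.629). Control 10 carried this difference, with a mean log2 level of 4.17. The other samples ending in 0 stood at 5.30 to 5.82 and those ending in M at 5.40 to 5.53. Read totals differed by -8.092 megareads on average and overlapped (108.9 to 152.6 in 0, 128.2 to 140.5 in M), which argues against depth. A batch of collection or library preparation and a difference between conceptuses cannot be told apart, since no label says what the character marks and each treatment group has 2 samples of each kind.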
